A study of Mus musculus with 18 samples.

How the data were processed

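Gene expression was measured in whole brains of 8-week-old C57BL/6 mice of 3 genotypes, wild type, ERalphaKO and ERbetaKO, the knockout labels naming the estrogen receptor targeted. Each genotype was represented by 3 female and 3 male samples, giving 18 Affymetrix mouse expression arrays in 6 groups. The labels number the samples of a group but do not say that each came from a separate animal, so p-values measure the spread between these samples. Per the labels' protocols, frozen brains were extracted with Trizol and cleaned on RNeasy columns, and 1 µg of total RNA was labelled with biotin.

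The deposited values are linear probe set intensities, and the submitters' processing notes name MAS5, with no version given in the sources used here. In every deposited column the 2% trimmed mean of the 45101 probe sets was 500, so each array had been scaled by the authors to one common target. The table holds no detection calls, so probe sets near background could be recognised only by their low signal. The number of arrays limits the precision.

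The 64 control probe sets were left out of all gene tests, which left 45037. The platform annotation gave 1 gene symbol for 34945 of these, several for 932 and none for 9160. Symbols were updated to the RefSeq annotation of GRCm38.p6 through the entrez identifier for 34741 probe sets and through the symbol for 143, and the older name was kept for 61. Probe sets with several symbols or none named no gene. The array's own annotation names no genome build, so the RefSeq table served only for names and for the order of genes along chromosomes, and no coordinates are given.

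Signals were scaled to a common trimmed mean and transformed as log2(signal + 63.63), the pseudocount being the 25th percentile of all non-control values. Log2 differences are on this scale and understate the change of weakly expressed genes. For each of 18193 genes the probe set with the highest mean was kept, and the 13072 genes at or above the 40th percentile of all probe sets, a log2 level of 7.58, were tested. A linear model with a mean for each of the 6 groups was fitted with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance, and p-values were adjusted by the Benjamini-Hochberg method at 0.05. The genotype comparisons averaged the female and the male difference. All adjusted p-values for genes come from limma. All arrays entered the fit so that the groups shared 1 estimate of the spread, with 12 residual degrees of freedom. Estrogen receptor probe sets were also tested in a fit without the filter, with unadjusted p.

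38 gene lists of cell types, brain regions, pathways and steroid biology were fixed before the data were examined and tested with limma's camera at a preset correlation of 0.01, and again with the correlation estimated for each list. For each list, the members past the threshold over all genes are given beside those past it when adjusted over the list alone. Genes within 100 annotated genes on either side of Esr1 and Esr2 were compared with all other genes by Fisher's exact test. Control probe set ratios were compared with two-sided exact permutation tests of 6 against 6 arrays, adjusted over 21 tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

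Named genes were chosen by a rule fixed before the data were examined. It took Esr1 and Esr2 in every case. For each knockout line against wild type it took the 8 largest rises and 8 largest falls among genes past the threshold that changed alike in both sexes and whose 6 values lay wholly above or below the 6 wild type values. For ERalphaKO against ERbetaKO it took 5 each way. For lists past the camera test, and always for estrogen responsive genes, hypothalamic neuropeptides and steroid receptors, it took up to 4 members with the smallest adjusted p. It also took up to 6 sex-dependent genes each way, up to 5 genes per interaction (or the 3 with the smallest p where none passed), up to 6 genes near each target, and Xist and Y-linked genes as label checks. Genes named outside this rule are described as chosen after their values were seen.

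The fit was tested on simulated data for the 13072 genes with 200 genes changed. The simulated noise was normal and independent between genes, without the tissue differences found between these arrays. The shares below hold for that setting and can be worse in the real data. For the comparison of ERalphaKO with wild type it recovered 37.8% of genes changed 1.3-fold, 78.2% of those changed 1.5-fold and 97.7% of those changed 2-fold, with 4% of calls false. For female against male wild type, with 3 arrays each, it recovered 12.8%, 44.8% and 88.3% of genes changed by those folds. Alternatives fixed beforehand were other pseudocounts, quantile and median scaling, other filters, all probe sets, no intensity trend, array weights, only the groups compared, a replicate block, and each array left out in turn. Alternatives added after the data were seen were a cerebellar marker score, a pituitary marker score or the Actb 3' over 5' ratio as a covariate, and a fit on only the arrays with a Pcp2 signal of 500 or more. That fit kept 4 wild type, 4 ERalphaKO and 3 ERbetaKO arrays, with only 1 ERbetaKO female. It had fewer residual degrees of freedom than the full fit, so a call lost there can reflect lost precision. Leaving out each array in turn for the gene lists, the neighbours of the targets and the overlap was also added later.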

Results

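The study compared the brains of wild type C57BL/6 mice with those of mice labelled as knockouts of estrogen receptor alpha (ERalphaKO, gene Esr1) or estrogen receptor beta (ERbetaKO, gene Esr2), in both sexes. The 18 arrays comprised 6 per genotype, 3 from females and 3 from males. Signals correlated at 0.940 to 0.984 between arrays of one group and at 0.930 to 0.980 between groups. Xist, the RNA that silences one X chromosome in females, had a signal of 4647 ± 432 in the 9 female arrays and 336 ± 84.4 (SD) in the 9 male arrays. The lowest female value was 3916 and the highest male value 449, so every array matched its labelled sex. The Y-linked genes Eif2s3y and Kdm5d were likewise higher in males, at 402 ± 119 against 7.52 ± 8.83 and at 386 ± 45.3 against 98.9 ± 45.4. The probe sets of Usp9y, Zfy2, Sry and Uba1y did not separate the sexes. Their means were 98.17, 44.65, 24.05 and 286.9 in males against 87.05, 76.1, 34.6 and 305.9 in females.

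The targeted genes were examined first. The single Esr2 probe set was higher, not lower, in the ERbetaKO-labelled arrays. Its signal was 271 ± 98 (SD, n = 6) there, 28.7 ± 11.4 in wild type and 33.2 ± 22.6 in ERalphaKO-labelled arrays, and the lowest of the 6 ERbetaKO-labelled values, 160.4, lay above all 12 others (exact permutation p = 0.00217 against wild type). The wild type signal lay near background, under the pseudocount of 63.63, so the size on the log2 scale depends on the pseudocount. It was 1.82 ± 0.16 (SE) here, 3.19 with a pseudocount of 1 and 1.03 with one at the median. Esr1 was read by 3 probe sets, all of low signal. The brightest gave 129 ± 21.6 in ERalphaKO-labelled and 143 ± 35.9 in wild type arrays, a log2 difference of -0.09 ± 0.13 (exact permutation p = 0.511, n = 6 each). The others were higher in the ERalphaKO-labelled arrays, at 230 ± 52.3 against 141 ± 50.7 and at 65.0 ± 20.6 against 38.6 ± 16.5 (exact permutation p = 0.0173 and 0.0455). In ERbetaKO-labelled arrays the 3 probe sets gave 197 ± 24.6, 97.5 ± 55.8 and 37.2 ± 11.3 in that order (exact permutation p = 0.0130, 0.160 and 0.929 against wild type, and 0.00217, 0.00649 and 0.0195 against ERalphaKO-labelled arrays). The brightest was thus highest there, with all 6 values above the 6 ERalphaKO-labelled ones, while the others were higher in ERalphaKO-labelled arrays. A probe set outside the disrupted part of a gene checks nothing, and the position of these probe sets against the disruptions is not known here. Because Esr2 ran against its label, the groups are called ERalphaKO-labelled and ERbetaKO-labelled, and every direction given for them rests on the labels.

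**Figure D1:**
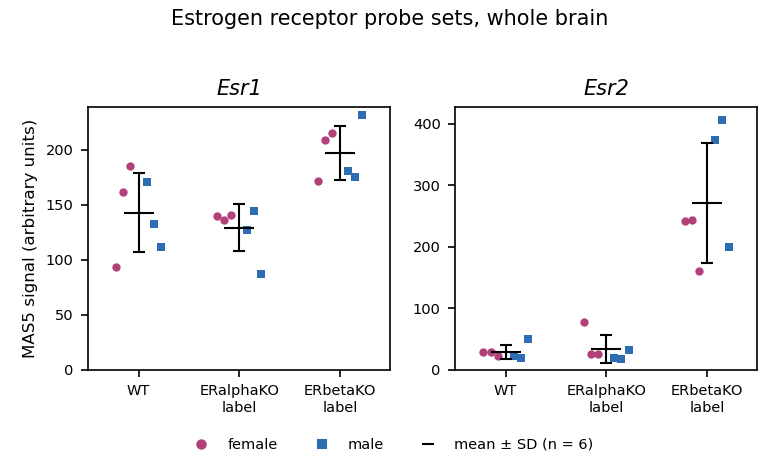
MAS5 signal (arbitrary units, linear axis) of the Esr1 probe set with the highest mean and of the Esr2 probe set in each of the 18 arrays, by labelled genotype. Points are arrays (circles female, squares male) and black marks the mean ± SD of 6; the ERbetaKO-labelled arrays lie between 160.4 and 407 for Esr2, above every other array.

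Tissue composition differed between arrays, and the Actb control ratio, unlike those of Gapdh and pyruvate carboxylase, differed between ERbetaKO-labelled and wild type arrays. Pcp2, a gene of cerebellar Purkinje cells, ranged from 117 to 10790, and lay under 500 on 2 wild type, 2 ERalphaKO-labelled and 3 ERbetaKO-labelled arrays. The cerebellar list had a median log2 difference of 0.04 in ERalphaKO-labelled and -0.94 in ERbetaKO-labelled brains (camera adjusted p = 0.921 and 0.0723). The pituitary growth hormone gene Gh ranged from 67.0 to 19900. The Actb 3' over 5' ratio, which grows as RNA is degraded or copied less fully, was 1.20 ± 0.0209 in wild type, 1.28 ± 0.0786 in ERalphaKO-labelled and 1.48 ± 0.182 in ERbetaKO-labelled arrays (exact permutation p = 0.0411 and 0.00217, adjusted p = 0.108 and 0.0455, n = 6 each). The same ratio of Gapdh was 0.769 ± 0.0213, 0.758 ± 0.0125 and 0.756 ± 0.0179 (exact permutation p = 0.310 and 0.294). That of pyruvate carboxylase was 2.60 ± 0.562, 2.38 ± 0.305 and 2.19 ± 0.226 (exact permutation p = 0.465 and 0.117). Neither rose with the Actb ratio. The highest poly-A spike-in signal, near background on all arrays, was lower in ERalphaKO-labelled arrays than in wild type, at 46.4 ± 9.06 against 76.5 ± 14.8 (exact permutation p = 0.00649, adjusted p = 0.0455).

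**Figure D2:**
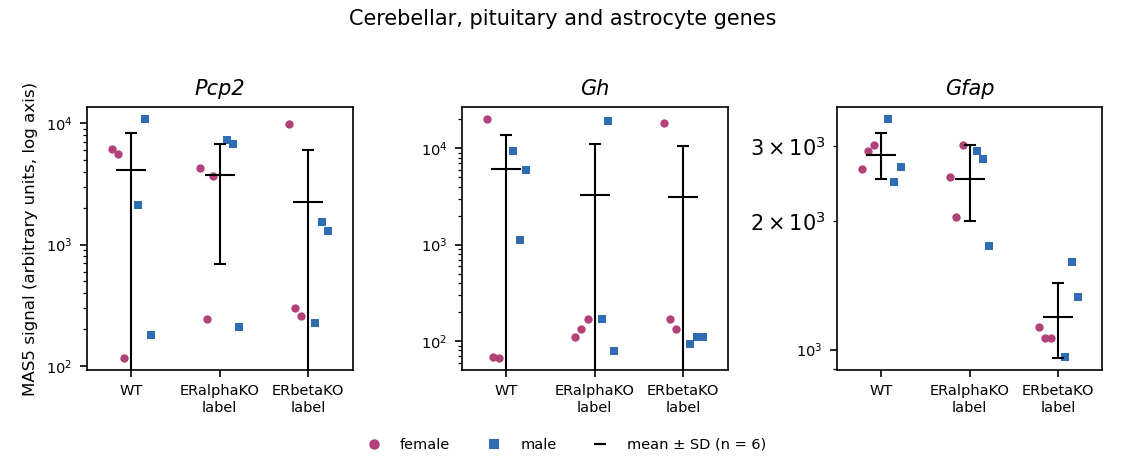
MAS5 signal (arbitrary units, log axes) of Pcp2 of the cerebellum, Gh of the pituitary and Gfap of astrocytes in each array by labelled genotype, with circles for females, squares for males and black marks for the mean ± SD of 6 (bars whose lower end is near or below 0 run off the log axis). Pcp2 and Gh vary widely within every genotype, while Gfap lies at 1609 or less in all ERbetaKO-labelled arrays.

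In ERalphaKO-labelled brains, genes induced by neuronal activity rose and a set of genes known to vary between mouse strains fell. Of the 20 immediate early genes tested, which encode transcription factors and effectors switched on within minutes of neuronal firing, 15 rose, none fell and 5 did not pass the test (16 rose when adjusted over the list alone). Fos rose from 759 ± 156 to 2535 ± 598, a log2 difference of 1.65 ± 0.12 (SE, limma adjusted p = 9.12e-07), and was higher in all 6 arrays than in any wild type array. Dusp1, a phosphatase that turns off MAP kinases, rose by 1.16 ± 0.10, and Npas4, Fosb, Nr4a3 and Egr2 rose by 1.18, 1.14, 1.02 and 1.00. The list passed camera (adjusted p = 1.54e-19, and adjusted p = 0.0229 with an estimated correlation). Fitted to the 11 arrays with a strong Pcp2 signal alone, Npas4, Nr4a3 and Egr2 no longer passed, at differences of 1.09, 0.94 and 0.83 (adjusted p of 0.0725, 0.0526 and 0.0595).

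Outside that list, Erdr1, Mid1 and Gm13306 rose by more than Fos, and the other changes named here were smaller than that of Fos. Erdr1, a stress-responsive gene of the pseudoautosomal region, rose by 3.76 ± 0.18, from 330 ± 62.1 to 5409 ± 1604 (limma adjusted p = 4.02e-09), and Mid1, a ubiquitin ligase gene that spans the boundary of that region, rose by 2.22 ± 0.28. Gm13306 rose by 1.76 ± 0.23 and Tmem267 by 1.18 ± 0.16. Wdfy1, an endosomal adaptor of Toll-like receptor signalling, fell by 1.36 ± 0.23 and Gabra2, a subunit of the GABA-A receptor, by 0.77 ± 0.13. Nnt, the mitochondrial transhydrogenase that is disrupted in one C57BL/6 substrain, fell by 0.76 ± 0.07, from 1423 ± 90.8 to 814 ± 77.1 (adjusted p = 1.50e-05). Wdfy1, Gabra2 and Nnt are 3 of the 6 tested strain variant genes, which as a list fell (camera adjusted p = 0.000756, and adjusted p = 0.0229 with an estimated correlation), with the same 3 past the threshold when adjusted over the list alone. 1700052K11Rik, Fam81a and Hnrnpl, an RNA-splicing factor, fell by 0.98, 0.87 and 0.81. Isl2, a transcription factor of motor neurons and retinal ganglion cells, fell by 0.93, but without ERalphaKO male replicate 2 its adjusted p was 0.0514. Troap fell by 0.70, a call lost on leaving out any one of 7 of the 12 arrays (adjusted p up to 0.0666). On the 11 arrays with a strong Pcp2 signal Isl2, Hnrnpl and Troap were at -1.14, -0.71 and -0.63 with adjusted p of 0.0677, 0.0956 and 0.105, and with the Actb ratio as a covariate Isl2 and Troap were at -0.79 and -0.61 with 0.0625 and 0.0831.

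**Figure D3:**
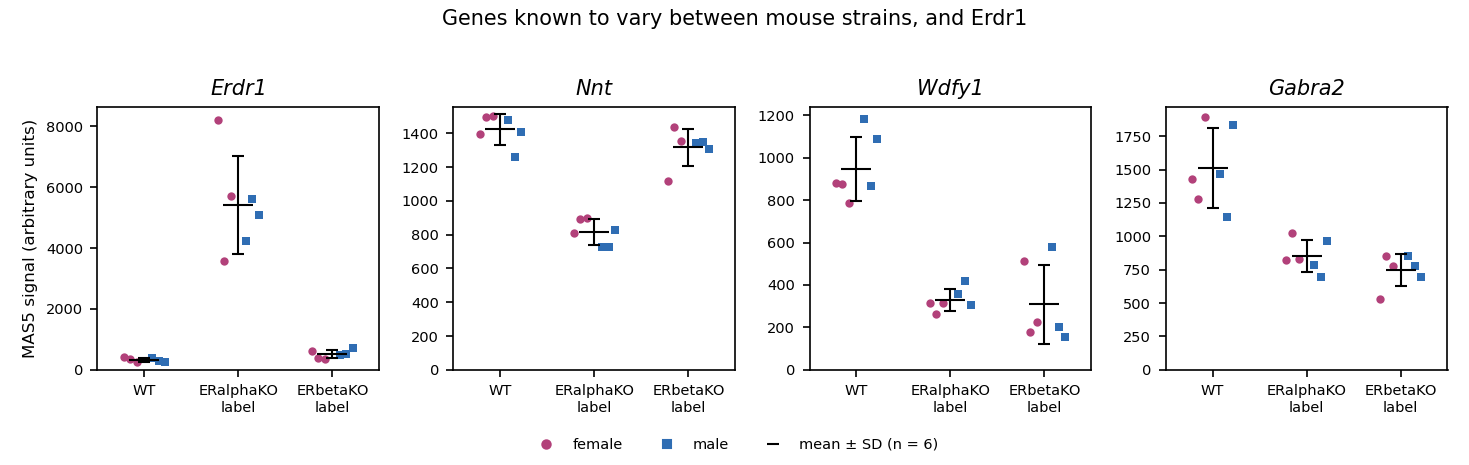
MAS5 signal (arbitrary units, linear axes starting at 0) of Erdr1, Nnt, Wdfy1 and Gabra2 in each array by labelled genotype, with circles for females, squares for males and black marks for the mean ± SD of 6. Erdr1 lies at 3588 or more and Nnt at 901 or less in the 6 ERalphaKO-labelled arrays, while Wdfy1 and Gabra2 are lower in both knockout-labelled genotypes than in wild type.

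3 further lists passed camera as lower in ERalphaKO-labelled brains, and none held with an estimated correlation. The astrocyte, microglia and oxidative phosphorylation list calls were lost on leaving out any one of 4, 7 and 6 of the 12 arrays. Their camera adjusted p then reached 0.157, 0.242 and 0.122. Of 15 astrocyte markers, 1 fell (3 when adjusted over the list alone), Aldoc, a glycolytic enzyme of astrocytes, by 0.49 ± 0.12, while Slc7a10, Ntsr2 and Glul had differences of -0.34, -0.29 and -0.24 (list adjusted p = 0.0416, and 0.971 as adjusted p with an estimated correlation). Of 15 microglia and macrophage markers, 2 fell, also when adjusted over the list alone, the complement gene C1qa by 0.53 and the lysosomal protease gene Ctss by 0.33, and Tmem119 and Laptm5 had -0.28 and -0.33 (list adjusted p = 0.0416, and adjusted p = 0.971 with an estimated correlation). Of 31 oxidative phosphorylation genes, Ndufa8 and Cox6c fell by 0.25 and 0.45, Sdhc and Ndufs8 rose by 0.25 and 0.40, and 27 did not pass (2 rose and 8 fell when adjusted over the list alone; list adjusted p = 0.0381, and adjusted p = 0.971 with an estimated correlation). After quantile normalization the astrocyte and oxidative phosphorylation lists no longer passed, and camera's direction for the latter turned, while Aldoc, Cox6c and Sdhc were at -0.15, -0.16 and 0.26 (adjusted p = 0.145, 0.0638 and 0.0587). On the arrays with a strong Pcp2 signal none of the 3 lists passed, with medians of -0.12, -0.17 and -0.11 (adjusted p = 0.294, 0.168 and 0.346), nor did Aldoc (-0.48), C1qa (-0.49), Ctss (-0.24), Ndufa8 (-0.21), Cox6c (-0.41) and Sdhc (0.21), with adjusted p of 0.0912, 0.105, 0.184, 0.222, 0.143 and 0.234. With the Actb ratio as a covariate the astrocyte and oxidative phosphorylation lists, at -0.17 and -0.13, had adjusted p of 0.0753 and 0.0767, and Aldoc, Ndufa8, Cox6c, Sdhc and Ndufs8, at -0.45, -0.26, -0.41, 0.26 and 0.37, had 0.0726, 0.0625, 0.108, 0.0835 and 0.119. The other probe set of Cox6c, the other one of Sdhc and 1 of the 5 others of Ndufs8 went the opposite way with an unadjusted p under 0.05, and 1 of Ndufs8 went the same way at that level. Each of these 7 single-gene calls was lost on leaving out any one of 3 to 10 of the 12 arrays (adjusted p up to 0.105), and the uncalled Slc7a10, Ntsr2 and Tmem119 passed under 6, 2 and 2 of 28 alternatives.

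In all, 876 of 13072 genes differed between ERalphaKO-labelled and wild type brains, 401 higher and 475 lower, with a median size of 0.38 on the log2 scale, and 15 changed more than 2-fold. For 445 of them the 6 values lay wholly on one side of the 6 wild type values; over all genes 4.65% did so, where chance gives 0.217%. The count was 396, 443, 489 and 539 without ERalphaKO male replicate 2, male replicate 1, female replicate 3 and female replicate 2, and 474, 544 and 579 without wild type male replicate 3, female replicate 1 and female replicate 3. It was 75 on the 11 arrays with a strong Pcp2 signal and 425 with the Actb 3' over 5' ratio as a covariate, and 1454 with the cerebellar score as a covariate, alternatives chosen after the data were seen, and 1559 with array weights.

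In ERbetaKO-labelled brains the immediate early genes also rose, and single markers of astrocytes and of oligodendrocytes and their precursors fell. Of the 20 immediate early genes, 14 rose, none fell and 6 did not pass (16 rose when adjusted over the list alone). Arc, which regulates AMPA receptor trafficking at synapses, rose from 585 ± 132 to 2929 ± 1022, a log2 difference of 2.14 ± 0.31 (SE, limma adjusted p = 0.00147). Egr2 rose by 1.73 ± 0.16, Fos by 1.71 ± 0.12, Dusp1 by 1.10 ± 0.10 and Junb by 1.04 ± 0.17, and Npas4 rose from 92.0 ± 36.4 to 318 ± 91.2. The Actb ratio was also higher in these arrays than in wild type, at 1.48 against 1.20. The lowest ratio here, 1.342, lay above the highest in wild type, 1.228. The ratio and this genotype thus go together. Calls lost with it as a covariate, here and below, cannot decide for or against RNA quality. The list passed camera at the preset correlation (adjusted p = 2.35e-15) and missed the threshold with an estimated one (adjusted p = 0.0759 with an estimated correlation). With that ratio as a covariate 4 members passed, the median SE being 0.28 in place of 0.16, and Arc, Npas4 and Junb, at 2.27, 1.31 and 1.15, had adjusted p of 0.0717, 0.130 and 0.0940.

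**Figure D4:**
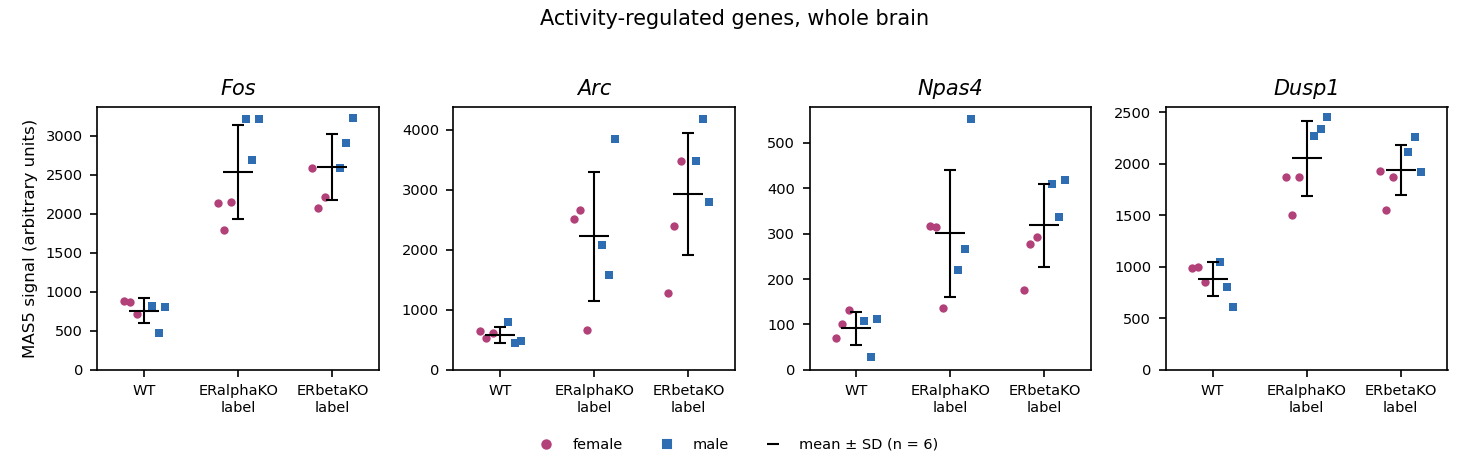
MAS5 signal (arbitrary units, linear axes starting at 0) of Fos, Arc, Npas4 and Dusp1 in each array by labelled genotype, with circles for females, squares for males and black marks for the mean ± SD of 6. Fos lies between 466 and 888 in wild type and at 1797 or more in every knockout-labelled array.

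Among glial genes, Gfap, the intermediate filament of astrocytes, fell by 1.23 ± 0.14, from 2869 ± 354 to 1193 ± 237 (limma adjusted p = 0.000184), and the astrocyte amino acid transporter gene Slc7a10 fell by 0.47 ± 0.10. The other 13 of 15 astrocyte markers did not pass, Fgfr3 and Aldh1l1 having -0.34 and -0.27 (7 fell when adjusted over the list alone; list adjusted p = 0.000238, and adjusted p = 0.621 with an estimated correlation). Of 9 oligodendrocyte precursor markers 3 fell (4 when adjusted over the list alone), the transcription factor gene Sox10 by 0.56, Cacng4 by 0.69 and Lhfpl3 by 0.46, while Olig2 had -0.42 (list adjusted p = 0.0271, and adjusted p = 0.621 with an estimated correlation). Of 13 oligodendrocyte and myelin markers 1 fell, also when adjusted over the list alone, the myelin transcription factor gene Myrf by 0.75, and Fa2h, Cnp and Mag had -0.43, -0.28 and -0.31 (list adjusted p = 0.0196, and adjusted p = 0.948 with an estimated correlation). The calls of Lhfpl3 and Myrf were lost on leaving out any one of 8 and of 11 of the 12 arrays. Those of the oligodendrocyte and precursor lists were lost on leaving out any one of 2 arrays each (camera adjusted p up to 0.0895 and 0.116). With the Actb ratio as a covariate Slc7a10, Cacng4, Lhfpl3 and Myrf were at -0.57, -0.80, -0.53 and -1.40, larger than without it, but with adjusted p of 0.144, 0.201, 0.275 and 0.0638. The arrays with a strong Pcp2 signal held only 1 ERbetaKO-labelled female. On them Sox10, Cacng4 and Lhfpl3, at -0.61, -0.72 and -0.36, no longer passed. Nor did the astrocyte list, with a median of -0.22. With the cerebellar score as a covariate the oligodendrocyte list no longer passed (median -0.18, adjusted p = 0.0745), and the cerebellar markers had a median of -0.94 in this comparison. With the filter at the 60th percentile neither the oligodendrocyte nor the precursor list passed (adjusted p = 0.0640 and 0.0832). The uncalled Fgfr3, Aldh1l1, Fa2h, Olig2 and Cnp passed under 6, 3, 2, 1 and 1 of 28 alternatives.

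The other changes that led the ERbetaKO-labelled comparison were of single genes. Tmem18, a nuclear envelope protein whose human counterpart lies beside variants associated with body weight, fell by 1.86 ± 0.09, from 898 ± 65.5 to 204 ± 39.1 (limma adjusted p = 3.09e-09). E2f5, a cell cycle transcription factor, fell by 1.79, Wdfy1 by 1.57, Foxo4, a transcription factor downstream of insulin signalling, by 1.49, Fgd6 by 1.35 and Ptpn23 by 1.20. The Fgd6 signal in ERbetaKO-labelled arrays, 43.7 ± 35.6 against 206 ± 68.9 in wild type, lay under the pseudocount, so the size of its difference depends on it (-0.74 with a pseudocount at the median). Cyp26b1, which degrades retinoic acid, fell by 1.18, a call lost on leaving out any one of 5 of the 12 arrays (adjusted p up to 0.0644). Sf3b3, a splicing factor, rose by 1.20 ± 0.16 and Gm13306 by 1.69 ± 0.23. With the Actb ratio as a covariate the differences of Wdfy1, Ptpn23, Sf3b3 and Cyp26b1 were -0.84, -0.83, 1.15 and -1.62, with adjusted p of 0.256, 0.268, 0.0850 and 0.145, and E2f5 was at -1.3 with an adjusted p of 0.363. On the arrays with a strong Pcp2 signal E2f5 and Cyp26b1 were at -1.76 and -0.97 with 0.0925 and 0.0546. Of the 6 strain variant genes, Wdfy1 and Gabra2 (by 0.95 ± 0.13) fell, also when adjusted over the list alone, while Nnt had -0.11 and Glo1 -0.22 (list adjusted p = 0.02, and adjusted p = 0.180 with an estimated correlation).

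The remaining lists past camera in this comparison had few or no called members. None of 10 thalamic markers passed (1, Prkcd, when adjusted over the list alone), with Prkcd at -0.97, Amotl1 at -0.39, Zic1 at -1.06 and Patj at 503 ± 544 against 956 ± 610 (list adjusted p = 0.0271, and adjusted p = 0.948 with an estimated correlation). None of 31 oxidative phosphorylation genes passed, also when adjusted over the list alone, with Sdhb, Uqcrc1, Ndufv1 and Ndufv2 between -0.24 and -0.22 (list adjusted p = 0.00154, and adjusted p = 0.948 with an estimated correlation). The cerebellar markers, a list that also holds Zic1, had a median of -0.94 in the same comparison and did not pass (adjusted p = 0.0723). Patj went from -0.996 to -0.40 with the cerebellar score as a covariate, where it passed (adjusted p = 0.0384). After quantile normalization the oligodendrocyte, precursor, thalamic, oxidative phosphorylation and strain variant lists no longer passed (adjusted p = 0.103, 0.0729, 0.0539, 0.114 and 0.0539). With the Actb ratio as a covariate the thalamic, oxidative phosphorylation and strain variant lists, at medians of -0.65, -0.09 and -0.24, had adjusted p of 0.0662, 0.258 and 0.147. As that ratio separated these arrays from wild type, calls lost with it can reflect lost precision. On the arrays with a strong Pcp2 signal the thalamic and oxidative phosphorylation lists, at -0.32 and -0.03, had 0.154 and 0.885. The thalamic list call was lost on leaving out any one of 4 of the 12 arrays (camera adjusted p up to 0.138). With the filter at the 60th percentile the thalamic and strain variant lists had 0.133 and 0.0640. The uncalled Sdhb, Uqcrc1, Ndufv1 and Ndufv2 passed under 5, 4, 2 and 2 of 28 alternatives, and Prkcd and Amotl1 under 3 each. In all, 980 genes differed from wild type, 381 higher and 599 lower (38.9% higher, against 47.9% with median centring), with 27 changed more than 2-fold and 441 with all 6 values on one side of wild type. The count was 500, 591 and 622 without ERbetaKO male replicate 1, ERbetaKO male replicate 2 and wild type male replicate 2, 235 on the arrays with a strong Pcp2 signal, 122 with the Actb ratio as a covariate and 1547 with array weights.

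None of 20 estrogen responsive genes, 18 steroid receptor and coregulator genes or 15 hypothalamic neuropeptide genes passed against wild type, over all genes or adjusted over the list alone. In ERalphaKO-labelled brains the members with the smallest p were Tff1 at -0.35, Ccnd1 at -0.16, Greb1 at -0.40 and Xbp1 at 0.19 for the first list, Esrrb at -0.41, Ep300 at 0.28, Ncoa3 at -0.25 and Nr3c1 at 0.11 for the second, and Pdyn at -0.26, Avp at 0.56, Pomc at -0.48 and Npy at -0.20 for the third. The Pomc signal of ERalphaKO male replicate 2 was 5755 and those of the other 5 lay between 231.7 and 412, so that the mean signal was higher than in wild type (1222 ± 2222 against 836 ± 369) while the log2 difference was negative. Without ERalphaKO male replicate 2 the Pomc difference was larger but still not past the threshold (adjusted p = 0.0549). In ERbetaKO-labelled brains the members with the smallest p were Bdnf at 0.37, Ctsd at -0.15, Xbp1 at 0.19 and Pgr at 0.21, then Esrra at -0.23, Gper1 at 0.23, Pgr again and Ep300 at -0.22, and Npvf at 0.37, Cartpt at -0.43, Nts at -0.47 and Gal at -0.32. The lists' camera adjusted p were 0.890, 0.608 and 0.890 for ERalphaKO-labelled brains and 0.939, 0.935 and 0.864 for ERbetaKO-labelled brains. Under some alternatives single members passed, with lowest adjusted p of 0.025 for Esrrb, 0.0257 for Tff1 and 0.0354 for Xbp1 in the former, under 4, 3 and 1 of 28, and of 0.0224 for Bdnf, 0.0339 for Pgr and 0.0424 for Esrra in the latter, under 2, 2 and 1 of 28. Pgr and Bdnf each stand in 2 of the lists.

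Members of other lists changed without the list passing camera, the lowest list adjusted p being 0.0559 for ERalphaKO-labelled and 0.0723 for ERbetaKO-labelled brains. Here and in the rest of this paragraph genes were chosen after their values were seen. Of 16 glucocorticoid responsive genes, 4 rose and 1 fell in ERalphaKO-labelled brains and 2 rose and 1 fell in ERbetaKO-labelled brains, with Sgk1, a kinase of ion transport, rising by 0.91 and 0.87 and Ddit4, an inhibitor of mTOR signalling, by 0.63 and 0.61 (5 and 4 called when adjusted over the list alone). Of 19 heat shock and chaperone genes, 4 rose, then 2 rose and 1 fell, with Hspa1b at 1.14 and 0.47 (6 and 4 when adjusted over the list alone). Of 18 circadian clock genes 2 rose in each comparison, Bhlhe40 and Per1, then Bhlhe40 and Ciart (3 and 3 when adjusted over the list alone). Per1 is also a glucocorticoid list member and Gabra2 a strain variant list member. Of 12 GABA receptor subunits Gabra2 and Gabbr1 fell in the first, and Gabra2 fell and Gabrg3 rose in the second (2 and 3 when adjusted over the list alone). Of 17 endothelial and mural markers, 2 fell, then 2 fell and 1 rose, with the tight junction gene Cldn5 falling by 0.40 and 0.39 (5 and 4 when adjusted over the list alone).

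The counts for the other lists, in ERalphaKO-labelled and then ERbetaKO-labelled brains, were as follows. 2 of 21 glutamate receptor subunits rose and then none, 2 of 20 synaptic genes fell in each, and none and then 2 of 13 excitatory neuron markers rose (2 and 0, 5 and 6, and 0 and 3 when adjusted over the list alone). 1 of 17 neurodegeneration genes rose and 1 fell, then 1 fell, and none and then 2 of 19 growth factor genes fell (6 and 2, and 0 and 5 when adjusted over the list alone), with Fgfr1, chosen after its value was seen, at -0.88. None of 13 oligodendrocyte and myelin, 9 oligodendrocyte precursor and 10 thalamic markers passed in the first comparison, and 1 of 15 microglia and macrophage markers fell in the second, with the same counts when adjusted over the list alone. 1 of 10 hippocampal markers rose and then 1 fell. 1 of 4 blood cell markers fell, 1 of 9 ependymal markers rose and 1 of 24 ribosomal protein genes fell in the first comparison, with none in the second. 1 of 9 X-linked genes rose and 1 fell in the first. None in the first and 1 in the second changed among 10 neurosteroid, 7 pituitary and 17 cholesterol synthesis genes, the first pair falling and the last rising. When adjusted over the list alone the counts were 1 and 1 for the hippocampal list, 1 and 0 for the blood cell and ependymal lists, 0 and 0 for the ribosomal list, 2 and 0 for the X-linked list, 0 and 3 for the neurosteroid list, 1 and 1 for the pituitary list and 0 and 1 for the cholesterol list. No member passed in either comparison among 14 choroid plexus, 14 meningeal, 16 inhibitory neuron, 13 striatal, 15 cerebellar, 11 olfactory bulb, 10 hindbrain, 14 interferon response and 3 Y-linked genes, and when adjusted over the list alone only 1 olfactory bulb gene did, in the second. Median and camera direction differed in sign for the hypothalamic neuropeptide, choroid plexus, ependymal, cholesterol and clock lists in the first comparison, and for the meningeal, blood cell, inhibitory neuron, hippocampal, hindbrain, GABA receptor and interferon lists in the second.

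The knockout-labelled genotypes were also compared with each other. Erdr1 was higher in ERalphaKO-labelled brains by 3.24 ± 0.18 and Tmem18 by 1.85 ± 0.09. Fgd6, Slc6a11, the GABA transporter of astrocytes, and Ssh3, a cofilin phosphatase, were higher by 1.40, 1.08 and 1.05, the first being 0.78 with a pseudocount at the median, as its ERbetaKO-labelled signal lay under the one used. Sf3b3, Il1f6, an interleukin of the IL-1 family, Ddit4l, Des, the muscle intermediate filament, and Fam110c were lower, by -1.46, -1.11, -0.95, -0.95 and -0.87. Altogether 2010 genes differed, 819 higher in ERalphaKO-labelled brains and 1191 higher in ERbetaKO-labelled brains (40.7% against 32.4% with median centring for the former), and 24 of them by more than 2-fold.

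No gene list passed camera between the knockout-labelled genotypes, the lowest adjusted p being 0.0693 for oligodendrocyte and myelin markers. Of the immediate early genes 1 was higher and 1 lower, also when adjusted over the list alone. Of the estrogen responsive genes 1 was called, also when adjusted over the list alone, Tff1 at -0.51, with Th at 0.86, Bdnf at -0.37 and Greb1 at -0.41 not past the threshold. Of the steroid receptors and coregulators 2 were called, also when adjusted over the list alone, the acetyltransferase gene Ep300 at 0.50 and the membrane estrogen receptor gene Gper1 at -0.40, with Crebbp at 0.21 and Esrra at 0.25 not past it. No hypothalamic neuropeptide passed, over all genes or adjusted over the list alone, with Npvf at -0.31, Nts at 0.67, Npy at -0.48 and Cartpt at 0.39. The count of genes was 1183, 1240, 1263 and 1336 without ERalphaKO male replicate 2, male replicate 1, female replicate 1 and female replicate 3, 1306 without ERbetaKO male replicate 2, 3827 with array weights, and 751 with the Actb ratio as a covariate, under which Slc6a11, Ep300 and Gper1, at 1.01, 0.48 and -0.35, no longer passed (adjusted p = 0.0577, 0.108 and 0.154). Gper1 was at -0.43 with 0.0865 on the arrays with a strong Pcp2 signal, the other probe set of Sf3b3 went the opposite way with an unadjusted p under 0.05, and the uncalled Th, Bdnf, Crebbp and Esrra passed under 8, 8, 5 and 2 of 28 alternatives. Among the neuropeptides Nts, Npy, Cartpt and Npvf passed under 3, 2, 1 and 1 alternatives (lowest adjusted p = 0.0277, 0.0194, 0.0461 and 0.0409).

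Both comparisons with wild type called 81 genes higher and 103 lower, and 3 in opposite directions. Independent lists of these sizes would share 11.7, 21.8 and 32.2. Unchanged groups simulated against the same wild type arrays shared 0 calls. Independent lists of the sizes called there would also share 0, so this simulation says little about genes that do change. With the wild type arrays split into separate sets of 3, over 18 splits, the comparisons shared medians of 3 higher, 3 lower and 0 opposite calls. Independent lists of the sizes called in those splits would share medians of 0.124, 0.204 and 0.309. Across genes, which are not independent replicates, the log2 differences correlated at 0.324, against 0.5 in the simulation. Over the splits the median correlation was 0.0871 (-0.09799 to 0.1835). The covariance of the log2 differences was 0.0160 against 0.0105 simulated, with a median of 0.00537 over the splits (-0.006997 to 0.01002). Both ranges over the splits included 0, so these values do not show a shared response across all genes. The count in the same direction was 106 without ERbetaKO male replicate 1, 38 with the Actb ratio as a covariate, 10 on the arrays with a strong Pcp2 signal and 328 with the cerebellar score as a covariate.

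Females and males differed at few genes. In wild type, Xist was higher in females by 3.60 ± 0.10 (limma adjusted p = 7.84e-13) and Kdm5d, a Y-linked histone demethylase gene, was lower by -1.45 ± 0.21 (adjusted p = 0.0159), the latter call being lost on leaving out any one of 5 of the 6 arrays (adjusted p up to 0.132). These were the 2 genes called, and 620 had an unadjusted p under 0.05 where 654 are due by chance. Over all genotypes 4 genes were called, Xist (3.58) and the X-linked Eif2s3x (0.32) higher in females and the Y-linked Kdm5d (-1.50) and Uty (-1.07) higher in males. On the arrays with a strong Pcp2 signal Eif2s3x and Uty, at 0.31 and -0.95, no longer passed (adjusted p = 0.989 and 0.155). The filter on signal left out Eif2s3y, and without that filter 3 genes were called in wild type and 6 over all genotypes. In wild type the X-linked list was higher in females (1 of 9 called, 5 when adjusted over the list alone; adjusted p = 4.43e-10, and adjusted p = 0.00283 with an estimated correlation). The Y-linked list was lower (adjusted p = 0.000931, and adjusted p = 0.0784 with an estimated correlation).

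Several autosomal lists also passed camera between the sexes in wild type without a called member. Oligodendrocyte and myelin markers were lower in females, with a median of -0.27 (adjusted p = 8.92e-05, and adjusted p = 0.527 with an estimated correlation), as were oxidative phosphorylation genes at -0.07 (adjusted p = 0.00594, and adjusted p = 0.987 with an estimated correlation). Immediate early genes were higher at 0.23 (adjusted p = 0.000931), as were excitatory neuron markers at 0.22 (adjusted p = 0.0182) and heat shock genes at 0.11 (adjusted p = 0.0155). With an estimated correlation the adjusted p of the last 3 was 0.527 each.

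No single gene had an effect of genotype that differed by sex in limma. For ERalphaKO-labelled brains 673 genes and for ERbetaKO-labelled brains 442 had an unadjusted p under 0.05, where 654 are due by chance. The smallest p belonged to Hmgxb4, Cetn1 and Tmem129, with female minus male effects of 0.99, 1.08 and 0.64, and to Col6a4, Snx25 and 4930442L01Rik, with 1.33, -0.69 and -0.76. Leaving out wild type male replicate 2 gave 3 genes in the first and 2 in the second, and leaving out ERbetaKO male replicate 1 gave 1 in the second.

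The share of genes called beside the targeted loci did not differ from that elsewhere by a test that passed the threshold with all arrays. Within 100 annotated genes of Esr1, 3 of 42 tested genes changed in ERalphaKO-labelled brains against 869 of 13000 elsewhere, an odds ratio of 1.07 (0.212 to 3.39, Fisher's exact p = 0.758). They were Ust (-0.40), Fbxo30 (0.36) and Zbtb2 (0.28). Within 100 genes of Esr2, 7 of 64 changed in ERbetaKO-labelled brains against 969 of 12979, an odds ratio of 1.52 (0.584 to 3.36, Fisher's exact p = 0.333). The 6 with the largest change were Frmd6 (0.67), Hif1a, the hypoxia-inducible factor (0.52), Fntb (-0.50), Snapc1 (-0.44), Dhrs7 (-0.36) and Arid4a (0.31). Without ERbetaKO female replicate 1 the odds ratio was 2.08 (Fisher's exact p = 0.0499). All of these single-gene calls but that of Frmd6 were lost on leaving out any one of 2 to 11 of the 12 arrays, and none of the 9 passed on the arrays with a strong Pcp2 signal or with the Actb ratio as a covariate, though each kept its direction. The other probe set of Arid4a and 1 of the 2 others of Hif1a went the opposite way with an unadjusted p under 0.05. Arid4a was also called in ERalphaKO-labelled brains, where it rose by 0.55. The other knockout-labelled genotype served as control for each locus. Near Esr2, 4 of the 64 genes changed in ERalphaKO-labelled brains, and near Esr1, 3 of the 42 changed in ERbetaKO-labelled brains.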

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

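The tests of clock phase, of genes beside Esr2 and of neighbouring calls were fixed before their results were seen, and the other tests of explanations here were chosen after the result was seen. Distances of single arrays were judged in sets of 6 arrays of one labelled genotype, where chance marks about 1 set in 20. Of 318 sets, 13 (4.1%) were marked, no more than chance gives. The gap of the farthest array as a share of the set's range is given for each.

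The Esr2 probe set was higher in the ERbetaKO-labelled arrays than in wild type, where its signal lay near background, so that the ratio of the means, 9.44, is no exact fold. All 6 of these arrays lay above the 12 others, wild type and ERalphaKO-labelled alike. This cannot decide on a swap of labels with another genotype of the series. A swap would leave only 1 genotype low if intact Esr2 gave a clear signal, and the wild type signal lay near background. A general rise of the locus is argued against by the 9 tested genes within 10 annotated genes of Esr2, whose median log2 difference was 0.093 against 1.82 for Esr2. An altered transcript that this probe set still reads may account for the signal, and it cannot be told apart from other origins because the probe positions against the disruption are not held here.

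Immediate early genes rose in both knockout-labelled genotypes, and the list score of all 12 knockout-labelled arrays lay above every wild type array. Cerebellar content is argued against as the whole cause, since 78.7% of the list's median difference remained with the cerebellar score, in whichever comparison kept less. RNA quality as read by Actb is argued against as the whole cause for ERalphaKO-labelled brains only, where 95.8% remained with that ratio. For ERbetaKO-labelled brains this covariate cannot decide, as the lowest Actb ratio there, 1.342, lay above the highest in wild type, 1.228. With either covariate the list still passed at camera's preset correlation. In ERbetaKO-labelled brains it missed the threshold with an estimated correlation even without a covariate (camera adjusted p = 0.0759). With the Actb ratio in ERbetaKO-labelled brains, calls went from 14 to 4 while the median went from 0.73 to 0.88 and the median SE from 0.16 to 0.28, as the ratio and that genotype go together, so most single calls there did not hold. A time of day that shifts the clock phase score by over 0.3, a bound set beforehand, is argued against for ERalphaKO-labelled brains. The score differed there by -0.0537 (95% interval -0.29 to 0.20) from wild type. For ERbetaKO-labelled brains the interval, -0.12 to 0.34, passed that bound. The score can take the same value at different hours, so another collection time is not excluded. Handling or collection of each genotype as its own batch stays open and cannot be told apart from loss of a receptor, which is also open, the lowest of the 4 differences within one sex being 0.52.

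Among genes known to vary between mouse strains, Wdfy1 and Gabra2 fell in both knockout-labelled genotypes and Nnt fell in ERalphaKO-labelled brains, although the labels give one strain. DNA of another strain kept near the targeted gene is argued against for these 3 genes, as 0 of them lie on the chromosome of the target (chromosomes 1, 5 and 13, against 10 for Esr1 and 12 for Esr2). Blocks of other background DNA elsewhere may contribute in ERbetaKO-labelled brains, where neighbouring genes were called in the same direction 1.56 times as often as after permuting positions (57 pairs against 36.6), above the 1.28 of genes that follow the cerebellar score; the difference of these ratios was not tested. In ERalphaKO-labelled brains the ratio was 0.998, below the 1.40 of the cerebellar genes, which argues against many such blocks but not against single variants. A difference between the lines that comes from the receptors was not tested.

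In wild type, Fos lay low on male replicate 2 (gap 0.654). In ERalphaKO-labelled arrays, Fosb (0.635) lay high and Snapc1 (0.782) low on male replicate 3, Pomc (0.84) high on male replicate 2, at 5755 against at most 412 elsewhere, Cacng4 (0.656) low on male replicate 1, Il1f6 (0.668) low on female replicate 1 and Zbtb2 (0.677) high on female replicate 2. The poly-A spike-in signal, near background on all arrays, was high on male replicate 1 (0.711). In ERbetaKO-labelled arrays, Pomc (0.669) and Patj (0.649) lay high on female replicate 1, Cetn1 (0.789) and the Actb ratio (0.745, a ratio of 1.84) high on female replicate 2, and Sf3b3 (0.66) low on male replicate 3.

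The genotype effect on several gene lists differed between the sexes by camera on the interaction, with no single gene called and none holding with an estimated correlation (adjusted p of 0.426 or more). For ERalphaKO-labelled brains the median female minus male effect was -0.55 for immediate early genes, which were higher than wild type by 0.52 in females and 1.09 in males, 0.41 for oligodendrocyte and myelin markers, -0.24 for excitatory neuron markers and -0.13 for heat shock genes. For ERbetaKO-labelled brains it was -0.56 for immediate early genes (0.52 and 1.03), 0.31 for oligodendrocyte and myelin markers, -0.48 for excitatory neuron markers, -0.17 for synaptic genes and 0.15 for oxidative phosphorylation.

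Probe sets without a gene name, which no comparison above used, also changed. Of 3375 past the filter, 477 were called in ERalphaKO-labelled brains, 373 higher and 104 lower, and 333 in ERbetaKO-labelled brains, 282 higher and 51 lower, whereas probe sets with 1 gene name split into 1075 higher and 832 lower and into 841 higher and 903 lower.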

How the results depend on the processing

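The fits on a cerebellar score, a pituitary score or the Actb ratio as covariates and on only the arrays with a strong Pcp2 signal, and leaving out arrays for lists, neighbours and overlap, were chosen after the data were seen. In ERbetaKO-labelled brains, calls lost with the Actb ratio or on the strong Pcp2 arrays can reflect lost precision. The ratio goes together with that genotype, and those arrays hold only 1 of its females. Keeping the deposited scale moved nothing, as every array already had one trimmed mean, and so tests nothing. Of 75 named calls, 44 were kept with the Actb ratio as a covariate, 45 on the strong Pcp2 arrays and 66 or more under each other alternative that keeps all arrays and genes; no called gene turned direction. Esr2 kept its direction and side of the threshold throughout (1.74 to 1.95 with single arrays left out), but its size followed the pseudocount, at 3.19 with a pseudocount of 1 and 1.03 with one at the median. With median centring, 47.9% of the genes called in ERbetaKO-labelled brains were higher in place of 38.9%, and 32.4% in place of 40.7% between the knockout-labelled genotypes. Signals near background, such as those of Esr1 and Esr2, limit what the arrays can show. Except where fewer samples or more probe sets were tested, the cause of a change was not tested.

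Testing all probe sets called 2450 probe sets for ERalphaKO-labelled and 2113 for ERbetaKO-labelled against wild type, 4173 between them, 7 between the sexes in wild type and 10 over all genotypes, several of which can share a gene or name none. Array weights gave 1559, 1547 and 3827 genes for the 3 genotype comparisons. The cerebellar score as a covariate gave 1454 for ERalphaKO-labelled brains and an overlap of 328. The Actb ratio as a covariate gave 425, 122 and 751, an overlap of 38, 3 and 4 gene lists, odds ratios of 0 near Esr1 and 0 near Esr2, Avp at -0.12, Pgr at -0.0935 and a hypothalamic list median of -0.14. The strong Pcp2 arrays gave 75 and 235 genes, 1 between the sexes in wild type and 2 over all genotypes, an overlap of 10, 2 lists for ERalphaKO-labelled brains, odds ratios of 0 near Esr1 and 0 near Esr2, and Esr1 at 0.0054.

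An estimated correlation left 2 lists for ERalphaKO-labelled and 0 for ERbetaKO-labelled brains. Quantile normalization left 2 lists for ERbetaKO-labelled brains, turned camera's direction at medians of -0.0324 for oxidative phosphorylation in ERalphaKO-labelled and of -0.0246 and -0.0329 for estrogen responsive genes and steroid receptors in ERbetaKO-labelled brains, and gave 0.732 near Esr1. Without a filter there were 8 lists for ERalphaKO-labelled brains, an estrogen responsive median of -0.0015, 0.530 near Esr1 and 1 gene whose ERalphaKO effect differed by sex. With the filter at the 60th percentile there were 3 lists for ERbetaKO-labelled brains, an estrogen responsive median of -0.0302 with camera's direction turned, 0.740 near Esr1, and 1 and 2 genes between the sexes in wild type and over all genotypes. With 200 genes either side the odds ratio near Esr1 was 0.872. For the sexes in wild type, a pseudocount of 1 gave 1 gene, one at the median gave 4, and only the groups compared gave 1.

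With single arrays left out, the counts ranged from 396 to 777, 500 to 1002 and 1183 to 2248 for the genotype comparisons, 1 to 4 and 4 to 5 for the sexes, 0 to 3 and 0 to 2 for the interactions, and 106 to 228 for the overlap. Lists ranged from 3 to 7 and 5 to 9, the odds ratios from 0 to 1.08 near Esr1 and 0.511 to 2.08 near Esr2, and Esr1 from -0.19 to -0.02. List medians ranged from -0.121 to 0.0114 and -0.09997 to 0.0583 for estrogen responsive genes, -0.17 to 0.16 and -0.19 to 0.11 for hypothalamic neuropeptides, and -0.0611 to -0.00809 for steroid receptors in ERbetaKO-labelled brains. Lists called with all arrays kept the sign of their median but not its size. In ERbetaKO-labelled brains oxidative phosphorylation ranged from -0.184 to -0.0730 and precursor markers from -0.307 to -0.154.

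The replicate numbers gave no clear sign of pairing. Pairs with the same number correlated at a median of 0.0188, and 14 of 45 above 0.1, while pairs with different numbers had a median of -0.00878. 5 of 18 arrays correlated best with one of their own number. Tissue composition also differed between arrays, so a weak pairing is not excluded. With the number as a block the genotype counts were 730, 852 and 1827, the sexes gave 2 and 4, the interactions 0 and 0, the lists 5 and 8, the odds ratios were 1.31 near Esr1 and 1.49 near Esr2, Esr1 was at -0.09 and Esr2 at 1.82, and the overlap was 157.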

Other observations

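The tests with sex redrawn for the interactions were chosen after the result was seen, and those for the other comparisons before. Some genes beyond the lists above, chosen after their values were seen, changed in the same direction in both knockout-labelled genotypes. E2f5 was lower by -1.74 in ERalphaKO-labelled and -1.79 in ERbetaKO-labelled brains, Foxo4 by -0.73 and -1.49, and the signalling genes Gnb1, a G protein subunit, by -0.77 and -0.85 and Ncs1, a neuronal calcium sensor, by -0.69 and -0.81. Klf10 and Gadd45b, both induced by growth signals or stress, were higher by 0.65 and 0.86 and by 0.79 and 0.67. The alternatives were not run for these genes, apart from E2f5 and Foxo4 in ERbetaKO-labelled brains.

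Other divisions of the same arrays were fitted with the division, the third genotype and sex as terms. In a mixed division the real genotype difference stays in the spread, which lowers its count. The test thus leans toward the real division, so chance is argued against but not excluded for the 3 genotype comparisons. In that model the real division gave 965 genes for ERalphaKO-labelled against wild type, 1048 for ERbetaKO-labelled against wild type and 2069 between them, and 1 of 100 divisions, the real one, gave as many in each case. The highest of the others gave 612, 6 and 1. The division with 612 genes had a gap in the cerebellar score of 1.51 (rank 3 of 100), but the divisions of rank 1 and 2 gave 1 and 0 genes, so what set it apart was not identified.

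For female against male over all genotypes, 2 of 100 divisions, the real one with 4 genes included, gave as many, a share under 0.05. The highest of the others gave 195, so a count of 4 does not by itself exclude chance. The division with 195 genes had a gap in the cerebellar score of 1.40 (rank 2 of 100), against 0.064 (rank 89) for the real one. No other division, that of rank 1 included, gave over 10 genes, so what set this one apart was not identified. For wild type alone the 10 divisions are too few for a share under 0.05; the real one gave 2 genes and the highest other 1. For the interactions the real divisions gave 0 genes, which all 100 divisions reached, as any count would. The highest others gave 177 and 43, with gaps in the cerebellar score of 1.96 (rank 1 of 100) and 1.10 (rank 11). The real divisions had gaps of 0.33 (rank 64) and 0.082 (rank 93). Whether cerebellar content gave the high counts was not tested.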
